A study of Mus musculus with 175 samples.

How the data were processed

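Single intraepithelial lymphocytes (IELs) of the mouse intestine were measured by Smart-seq2, a plate-based method in which full-length cDNA is made from poly(A) RNA of 1 cell per well. Cells had been stained with a tetramer, a reagent of linked MHC molecules that carry a peptide, here for the β-N-acetylhexosaminidase of the gut commensal Parabacteroides goldsteinii. Each cell was labelled as tetramer-positive or tetramer-negative and as 1 of 3 cell types, CD4IEL, Pre-IEL or Conventional. The rule by which cells were assigned to a type is not given in the sources used here, so a gene that served to assign types is a check on the labels rather than a finding. Cells came from 3 mice and 4 plates. Every plate held cells of both tetramer classes, but tetramer-negative cells stood in the upper rows of wells and tetramer-positive cells in the lower rows, so class and well row cannot be separated.

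Per the labels, reads were aligned with STAR (version not stated), quantified with RSEM 1.3.1 and handled in Seurat 4.1.0 on the mm10 mouse genome. The deposited values per cell are RSEM expected counts, estimated read counts per gene before any normalization, and the authors give no molecular identifiers. A read is therefore not an independent molecule, and confidence intervals and floors cover counting error only. In the files, 0.716% of the values were not whole. The authors' normalized matrix holds the natural log of 1 plus the count scaled to 10000 per cell, and the expected counts gave its values back to within 5.3e-15. A joint count table and cell map coordinates were not used here. Genes were identified by versioned Ensembl identifiers, of which 55141 of 55401 had coordinates in GENCODE release M21 on mm10.

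Expected counts were rounded per cell and summed per mouse, tetramer class and cell type, which gave 18 sums in 6 groups with the mouse as replicate (n = 3). Levels are normalized counts (CPM, scaled to 1e6 by the edgeR library size) as the mean over the 3 mice with its SD. For a cell type, each mouse's value is the mean of its tetramer-positive and tetramer-negative sums, and for a tetramer class over types the mean of its 3 type sums. Where all sums of a group were at 0, a fold is a lower bound for counting error only, against a floor of 3 counts over the whole group. It does not cover which cells were sampled, and a further cell with reads could lower it greatly. Folds are ratios of mean CPM, while fitted log2 changes average the groups on the log scale and are larger where some groups are at 0. All 18 sums were fitted together in edgeR 4.0.16 with TMM factors (0.712 to 1.678), filterByExpr by group, which kept 8835 genes, and the robust quasi-likelihood test on 12 residual degrees of freedom. Adjusted p-values follow Benjamini and Hochberg, with a threshold of 0.05. The contrasts were tetramer-positive against tetramer-negative as a mean over the cell types and within each type, each pair of cell types over both tetramer classes, and the difference of the tetramer contrast between types. The common biological coefficient of variation of the sums was 2.21. Because the 3 mice gave sums to every group, the pairing was checked over 4418 genes. The mean correlation between sums of the same mouse was 0.0169, 0.00457 and 0.0144 for the 3 mice (15 pairs each), against -0.00596 between mice (90 pairs), and the mouse was used as a block in an alternative.

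There were 23 gene lists, tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01 and adjusted over the lists of a contrast. Camera with an estimated correlation and fry were alternatives. Lists covered cytotoxic and NK-like genes, epithelial residency, recirculating and naive-like genes, CD4 helper identity, regulatory T cells, inhibitory receptors, Th1, Th2, Th17, follicular helper cells, T cell receptor signalling, proliferation, type I interferon, TGF-beta, retinoic acid, oxidative phosphorylation, glycolysis, heat shock and dissociation, and mitochondrially encoded genes. Further lists held markers of γδ and CD8αβ T cells, epithelial cells, B and plasma cells, and myeloid cells, which a sort could have let through.

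Named genes followed a fixed rule. In the tetramer contrast over types and in CD4IEL against Conventional, the 10 largest changes in each direction were taken among genes that passed and had the same sign in all 3 mice, and in other contrasts the 5 largest. T cell receptor V, D and J genes, immunoglobulin genes and unnamed models were left out of that choice. Where fewer than 6 genes passed, the 5 higher and 5 lower genes with the smallest p are given as values that did not pass. From each list came up to 4 members that passed, or the 2 with the smallest p. Cd4, Cd8a, Itgae, Foxp3, Zbtb7b, Runx3, Il10, Ctla4, Lag3 and Gzmb were always looked up. Some genes that this rule chose are not reported here. The groups, contrasts, tests, lists and this rule were fixed before the data were examined.

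Cell type shares were computed per mouse and tetramer class and compared by two-sided exact permutation tests over 3 mice per class, whose smallest possible p is 0.1. All exact permutation tests here treat the values as unpaired, although the same 3 mice gave both sides. The side in each mouse is the paired reading, and no paired exact test over 3 mice can fall under 0.05. Shares of cells with a transcript of 14 genes were computed after thinning each cell to 120000 counts, which left 157 cells. A T cell receptor V gene was called in a cell from at least 10 counts, as a Trav family and a Trbv gene. Chance that 2 cells of a sample share a Trbv gene (Simpson index) was compared in the same way. Clopper-Pearson intervals are at 95%.

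Alternatives were the replicate block, DESeq2 1.42.0, RLE factors, no filter on low counts, limma on the mean CPM over cells with a pseudocount of 1 or 5, limma voom with sample quality weights, sums of at least 4 cells, cells with at least 1000 genes, each mouse or plate left out, and the authors' normalized values. Chosen after seeing the data were a limma test on the share of cells with a read per sum (arcsine square root, weighted by cells, genes read in at least 9 cells), camera on those shares, 5 random draws of both tetramer classes to equal cell numbers, tetramer-negative cells alone, and lists without Cd4, Cd8a and Itgae, the surface markers by which these cell types are commonly sorted.

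The fit was tested on simulated data. At a coefficient of variation of 0.4, edgeR recovered 100% of 4-fold and 98% of 16-fold changes in the tetramer contrast, with 5 false calls among 8835 genes. At the observed 2.21 it recovered 0% of either, so a gene without a call is not shown to differ by less than such a fold. In the tetramer contrast the share test recovered 38% of differences of 0.25 in the share of cells and 99% of differences of 0.5, with 14 false calls. For CD4IEL against Conventional cells it recovered 37% and 99%, with 8 false calls. These simulated shares were only raised and had no spread between mice beyond the drawing of cells, a kinder setting than the real data. In CD4IEL against Conventional cells, camera called a list moved by 4-fold in 13 of 20 runs and called 0 of 420 unmoved lists. These lists held random genes that were drawn independently of each other. The runs therefore do not show how often camera falsely calls a real list, whose members may vary together. Calculations used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.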

Results

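The data were transcript counts of 175 single CD4 T cells from the intestinal epithelium of 3 mice. Of these, 53 were tetramer-positive (15 CD4IEL, 13 Pre-IEL and 25 Conventional), and the tetramer-negative ones were 68 CD4IEL, 29 Pre-IEL and 25 Conventional cells. The 3 mice gave 44, 41 and 37 tetramer-negative and 22, 22 and 9 tetramer-positive cells, so the sums by mouse, class and type held 2 to 27 cells and 522001 to 6767618 counts. Total counts per cell ran from 33170 to 519947 (median 229842), with 353 to 3393 genes detected (median 1507) and 0.411% to 9.711% mitochondrially encoded counts (median 2.797%). Median depth was 227667 counts in tetramer-negative and 255864 in tetramer-positive cells. It was 227841 in CD4IEL, 241026 in Pre-IEL and 237607.5 in Conventional cells. The 4 plates had median depths of 208511, 246225, 312880 and 142153.5 counts, and 27 cells had fewer than 1000 genes.

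Transcripts of the surface markers followed the labels. Cd8a, the CD8 alpha chain, was read in 60 of 83 CD4IEL, 0 of 42 Pre-IEL and 2 of 50 Conventional cells, at 1253.5 ± 268.7, 0 and 0.106 ± 0.183 CPM (SD, n = 3 mice). Itgae, the CD103 integrin chain that binds E-cadherin on epithelial cells, stood at 2098.2 ± 250.8 CPM in CD4IEL, 774 ± 283.2 in Pre-IEL and 30.2 ± 52.1 in Conventional cells. Cd4 stood at 703.5 ± 28.5 CPM in CD4IEL, 657.6 ± 345.9 in Pre-IEL and 818.2 ± 201.8 in Conventional cells. Foxp3, the regulatory T cell factor, and Zbtb7b, the CD4 lineage factor ThPOK, were at 0 CPM in the sums of CD4IEL and of Conventional cells. Both were also rarely read in Pre-IEL, in 5.25% and 2.08% of cells (means of 3 mice). Their values of 0 therefore lie at the limit of detection and do not show that the factors were absent.

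Whether cells that bind the tetramer take up the same epithelial states as other cells was asked first from the cell type labels. CD4IEL made up 31.5% ± 11.4 of tetramer-positive and 55.3% ± 8.21 of tetramer-negative cells (SD, n = 3 mice), and the share was lower among tetramer-positive cells in 3 of 3 mice. Conventional cells made up 44.4% ± 10.6 of tetramer-positive and 20.5% ± 3.39 of tetramer-negative cells, higher in 3 of 3 mice. Pre-IEL took nearly equal shares, 24.1% ± 7 and 24.2% ± 9.6. The exact two-sided permutation p was 0.1 for CD4IEL and for Conventional cells, the smallest that 3 mice against 3 can give. It was 1 for Pre-IEL, in a family of 3 types. The test leaves out the pairing, although each mouse gave both classes. By mouse, the CD4IEL share of tetramer-positive cells was 22.7% (Clopper-Pearson 95% interval 7.82% to 45.4%), 27.3% (10.7% to 50.2%) and 44.4% (13.7% to 78.8%). Among tetramer-negative cells it was 61.4% (45.5% to 75.6%), 58.5% (42.1% to 73.7%) and 46% (29.5% to 63.1%), so the intervals of mouse 3, with 9 tetramer-positive cells, overlapped almost wholly. Within each of the 4 plates CD4IEL were rarer among tetramer-positive cells, at 36.8% against 60%, 40% against 48.5%, 18.8% against 55.2% and 12.5% against 60%.

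**Figure D1:**
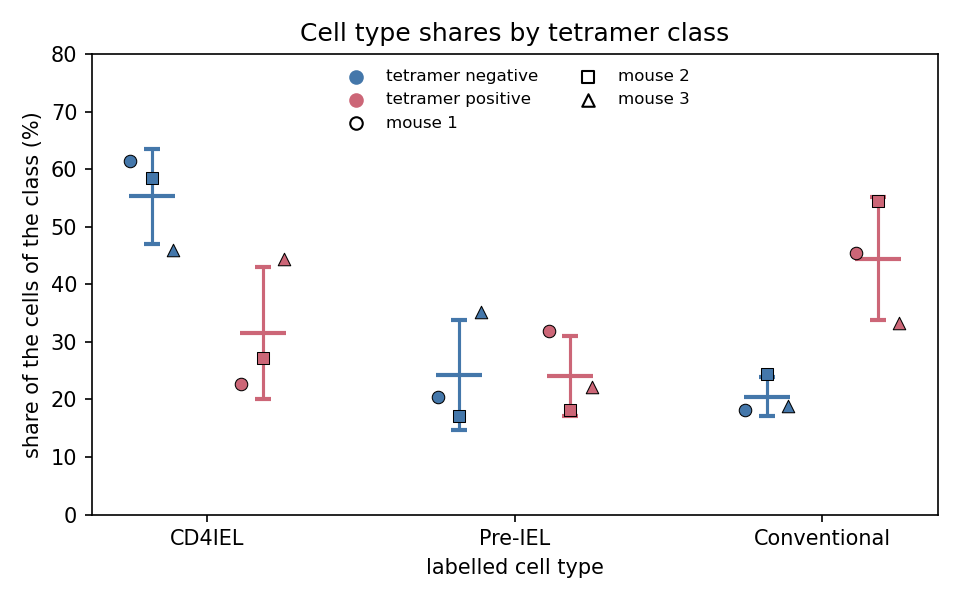
Share of cells in percent that carry each cell type label, by tetramer class; points are the 3 mice and the line is their mean. CD4IEL averaged 31.5% of tetramer-positive and 55.3% of tetramer-negative cells, and Conventional cells 44.4% and 20.5%.

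Within equal weights of the 3 cell types, tetramer-positive and tetramer-negative cells differed in no single gene that passed the test. Mipep, a mitochondrial peptidase, stood at 66.9 ± 7.17 CPM in tetramer-positive and 0 in tetramer-negative sums (n = 3 mice, 5 against 0 cells, at least 518.9-fold higher, edgeR adjusted p = 0.182), and did not pass. The same adjusted p belonged to the other values nearest the threshold. Higher among them were Unkl (117.7 ± 51.7 against 30.2 ± 14.4 CPM), Gpc1 (46.1 ± 39.9 against 0), Trp53rka (46.8 ± 29.5 against 0) and Sik2 (102.7 ± 120.3 against 5 ± 4.33). Lower were Vps4b, an ATPase of membrane scission (1.08 ± 1.87 against 192.8 ± 29.7), Clcn3, Hps5 (0 against 83.2 ± 52.4) and Setd2 (24.8 ± 26.5 against 170.8 ± 131.9). Gzmb, the granule protease granzyme B, had 987.2 ± 153.9 against 2160.3 ± 1122.7 CPM and was lower in 3 of 3 mice without passing. Cd8a had 128.5 ± 44.1 against 707.2 ± 204.6, Itgae 737.8 ± 257.6 against 1197.1 ± 102.1 and Cd4 859.8 ± 312.3 against 593.1 ± 79. Regulatory and inhibitory genes also did not pass. Ctla4 had 702.1 ± 729.8 against 1136.4 ± 277, Lag3 220.2 ± 180.3 against 338.3 ± 137.9, Il10 66.4 ± 67.6 against 116.8 ± 143.4 and Runx3 77.6 ± 49.8 against 107.5 ± 49.5 CPM, and Foxp3 was read in 1 cell of each class.

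By list, recirculating and naive-like genes fell in tetramer-positive cells (12 of 14 members with a lower mean, camera adjusted p = 0.000432, adjusted p = 0.222 with an estimated correlation). S1pr1, the receptor for exit from tissue, stood at 7.51 ± 13 against 140 ± 78.6 CPM and S1pr4 at 22.7 ± 20.3 against 92.7 ± 43.8. Adjusted over the list alone 3 members passed, all lower, against 0 over all genes. Proliferation genes rose (20 of 24 members higher, adjusted p = 0.000386, adjusted p = 0.835 with an estimated correlation). Of the replication helicase genes among them, Mcm3 stood at 155.9 ± 109.9 against 26.3 ± 11.3 CPM and Mcm2 at 149.1 ± 136.2 against 40.2 ± 31.6. T cell receptor signalling genes fell (19 of 24 lower, adjusted p = 0.0439, adjusted p = 0.835 with an estimated correlation), among them Zfp36 at 68 ± 12.9 against 286.6 ± 125.4. Irf4, a factor induced by receptor signalling, had 33.7 ± 29.2 against 146.4 ± 60.7. edgeR called 0 of 8835 genes, with 1201 at an unadjusted p under 0.05 (197 higher and 1004 lower). DESeq2 called 1667, limma voom 46 and the share of cells with a read 0. The median log2 change of all genes was -0.64, and -0.46 with RLE factors, so single values lean lower in tetramer-positive sums, which hold fewer cells. In 5 draws to equal cell numbers the recirculating list passed in 3, proliferation in 4 and T cell receptor signalling in 1. With each of the 3 mice left out in turn, recirculating and proliferation genes passed in 2 (camera adjusted p up to 0.0737 for each). T cell receptor signalling then passed in 0 (0.0874 to 0.167).

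Within CD4IEL, the tetramer contrast set 15 cells against 68. Il27ra, a chain of the interleukin-27 receptor, was read in 0 tetramer-positive and 19 tetramer-negative cells, 0 against 285.7 ± 54.2 CPM (at least 343.7-fold lower, edgeR adjusted p = 0.0936). It did not pass. Other low values were Tinf2 (0 against 268.4 ± 100.7), Zwint (0 against 175.6 ± 134.9) and Cept1 (0 against 246 ± 93.4), and higher ones Sdc4, Tmem176a, Ly6a, Ell2 and Mipep (167 ± 71.1 against 0, 3 against 0 cells, adjusted p = 0.392). Cytotoxic and NK-like genes fell as a list (22 of 23 lower, camera adjusted p = 0.00125, adjusted p = 0.694 with an estimated correlation). The chemokine gene Ccl4 stood at 0 against 323.7 ± 37.3 CPM (at least 389.5-fold lower) and Gzmb at 1868.7 ± 933.1 against 4336.6 ± 1972.2, and neither passed. Cd8a had 385.4 ± 132.5 against 2121.5 ± 613.9 and Lag3 270.7 ± 95.2 against 606.4 ± 135.2. The proliferation list was called up (12 of 24 members higher and 11 lower, adjusted p = 0.024, adjusted p = 0.882 with an estimated correlation). So was the mitochondrially encoded list, a sign of RNA quality (adjusted p = 0.024, adjusted p = 0.882 with an estimated correlation), whose median log2 change of -0.18 had the opposite sign to its test. edgeR called 0 genes, with 934 at an unadjusted p under 0.05 (97 higher and 837 lower), DESeq2 1077 (47 higher and 1030 lower), limma voom 600 and the share of cells 0. The median log2 change of all genes was -0.87, so most members of any list lean lower here, and in 5 draws to equal cell numbers it was 0. In these draws the camera adjusted p was 0.000126 to 0.0191 for cytotoxic, 0.142 to 0.639 for proliferation and 0.18 to 0.998 for mitochondrially encoded genes. Without 1 mouse that of cytotoxic genes reached 0.0735.

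Within Conventional cells, 25 in each class, recirculating and naive-like genes fell in tetramer-positive cells (12 of 14 lower, camera adjusted p = 1.55e-06, adjusted p = 0.0385 with an estimated correlation). S1pr1, the receptor for exit from tissue, was read in 3 against 9 cells, 22.5 ± 39 against 367.7 ± 230.7 CPM. Tcf7, a factor of naive and memory T cells, stood at 183.7 ± 91.4 against 889.4 ± 568.6. Neither gene passed alone. With an estimated correlation the list had adjusted p = 0.947 without mouse 1 and adjusted p = 0.148 without mouse 3, and in 5 draws to equal cell numbers the camera adjusted p ran from 7.24e-08 to 0.283. Single genes nearest the threshold (edgeR adjusted p = 0.397) were higher for Rab18 (321.1 ± 185.9 against 0, 6 against 0 cells, at least 555.4-fold), Cst7 (69.3 ± 84.8 against 0), Itgae (60.4 ± 104.3 against 0), Efhd2 and Baiap3. They were lower for Smarca4 (0 against 157 ± 76.1), Pebp1 (0 against 178.8 ± 138.5), Vps4b (0 against 167 ± 156.6), Dapk2 and Psmc2. edgeR called 0 genes, with 913 at an unadjusted p under 0.05, DESeq2 1087, limma voom 30 and the share of cells 0.

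Within Pre-IEL, 13 tetramer-positive against 29 tetramer-negative cells, proliferation genes rose as a list (20 of 24 higher, camera adjusted p = 0.001, adjusted p = 0.832 with an estimated correlation), with Mcm3 at 225.9 ± 213.2 against 0 CPM. In 5 draws to equal cell numbers it passed in 3. Single genes nearest the threshold (edgeR adjusted p = 0.383) were Unkl (217.4 ± 165.5 against 0, 4 against 0 cells, at least 424.4-fold higher), Trgc4, Kit (213.6 ± 298.8 against 0.17), Uqcrb and Htatsf1. On the lower side were Bcl10, an adaptor from the antigen receptor to NF-kappaB (0 against 329.4 ± 95.7, 0 against 14 cells, at least 423.1-fold lower), Vps37b (482.2 ± 235.8 against 2663.9 ± 2078.1), Dgat1, Tm9sf2 and Tagap (0 against 158.8 ± 183.2). edgeR called 0 genes, with 974 at an unadjusted p under 0.05, DESeq2 1192, limma voom 35 and the share of cells 0.

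CD4IEL were set against Conventional cells over both tetramer classes (83 against 50 cells). In CD4IEL, 6 genes rose. Fcer1g, the signalling adaptor shared by Fc and some NK receptors (ENSMUSG00000058715.11, mm10 chromosome 1, 171229572 to 171234365), stood at 472.9 ± 348 CPM against 0 (SD, n = 3 mice, 18 against 0 cells, 12 of them from mouse 2, at least 1749.4-fold, edgeR adjusted p = 0.0193). Trgc4, a constant gene of the T cell receptor gamma chain (ENSMUSG00000076757.9, chromosome 13, 19344558 to 19352756), stood at 411.5 ± 32.1 against 0 (35 against 0 cells, at least 1522.2-fold, adjusted p = 0.0193). Gamma constant genes have near-identical copies, and reads shared between copies were divided by the authors' quantification. Dapk2, a calmodulin-regulated death-associated kinase (ENSMUSG00000032380.9, chromosome 9, 66158223 to 66272242), was 69.8-fold higher at 648.8 ± 92.1 against 9.3 ± 16.1 (adjusted p = 0.0193). Cst7, cystatin F, an inhibitor of the proteases that activate granzymes (ENSMUSG00000068129.5, chromosome 2, 150570415 to 150578944), was 18.7-fold higher at 648.4 ± 292.5 against 34.7 ± 42.4 (adjusted p = 0.0193). The markers Cd8a (ENSMUSG00000053977.13, chromosome 6, 71373427 to 71379173, adjusted p = 4.2e-07) and Itgae (ENSMUSG00000005947.11, chromosome 11, 73090583 to 73147446, 69.5-fold, adjusted p = 0.0324) completed the 6.

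Of these genes, only Cd8a passed with each of the 3 mice left out in turn. Without 1 mouse, Fcer1g had adjusted p from 0.0502 to 0.59, Trgc4 from 0.189 to 0.282 and Cst7 from 0.0516 to 0.303, Dapk2 was lost without mouse 1 (0.059) and Itgae without mouse 3 (0.506). In tetramer-negative cells alone, chosen after seeing the data, Fcer1g (adjusted p = 0.0655), Trgc4 (0.156) and Dapk2 (0.393, fitted log2 change 5.06 against 9.24 with all cells) were lost. Without plate 2 or plate 3 so were Trgc4 (0.0922 and 0.0753) and Cst7 (0.0909 and 0.0658), and Itgae was lost without plate 3 (0.185) and in sums of at least 4 cells (0.105). On the mean CPM over cells Fcer1g had 0.064 and Cst7 0.0791, and in cells with at least 1000 genes Fcer1g had 0.0663. Each of these genes kept its direction.

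A test on the share of cells with a read, chosen after seeing the data because the sums rest on few cells, called 42 genes (31 higher and 11 lower) and 70 with the mouse as block. Of the 42, 6 were shared with the 7 of edgeR. The chemokine gene Ccl5 was read in 81 of 83 CD4IEL and 7 of 50 Conventional cells, 12278.6 ± 1080 against 83.9 ± 114.2 CPM (adjusted p = 8.05e-16 by shares), and the granule protease gene Gzma in 72 and 2 cells, 14590.8 ± 1319 against 551.7 ± 954.9 (1.71e-13). Cd7 was read in 71 and 3 cells, Nkg7, a granule membrane protein gene, in 74 and 10, Ctsw in 54 and 6, Gzmb in 54 and 8, and Runx3, a factor of the cytotoxic lineage, in 31 and 4. The NK receptor genes Klrd1 (20 against 0 cells, 12 of the 20 from mouse 2), Cd160 (33 against 3) and Cd244a (27 against 1) were also read in a larger share of CD4IEL. So were the collagen-binding integrin gene Itga1 (29 against 1), Jaml (36 against 1) and Gpr55 (24 against 0). Read in a smaller share were Cd28, the costimulatory receptor gene (10 against 34 cells, 161.6 ± 63.2 against 947.9 ± 397.6 CPM, 0.000113 by shares), Il7r (5 against 16), Tcf7 (6 against 21), Tnfsf8 (6 against 21), Sik1 (12 against 25), Cd2 (4 against 18), Gramd3 (2 against 16) and the cytokine gene Il17a (1 against 14). None of the genes of this paragraph passed in edgeR.

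Cytotoxic and NK-like genes rose together in CD4IEL (22 of 23 tested members higher, camera adjusted p = 1.33e-18, adjusted p = 0.00427 with an estimated correlation), with 2 passing over all genes and 13 adjusted over the list alone. Without mouse 2 this list had adjusted p = 0.176 and without mouse 3 adjusted p = 0.062 with an estimated correlation. Epithelial residency genes rose (17 of 21 higher, adjusted p = 1e-09, adjusted p = 0.0386 with an estimated correlation), with 2 passing and 8 adjusted over the list alone, and without Cd8a, Itgae and Cd4 this list had adjusted p = 0.109 with an estimated correlation. It was also lost there without any 1 mouse (adjusted p from 0.082 to 0.381). Recirculating and naive-like genes fell (13 of 14 lower, adjusted p = 4.62e-16, adjusted p = 0.000929 with an estimated correlation). Of its members 0 passed over all genes and 6, all lower, adjusted over the list alone, among them values of Il7r (47.7 ± 13.1 against 499.8 ± 157.5 CPM) and Tcf7 (45.7 ± 43.8 against 536.6 ± 318.1). Markers of γδ and CD8αβ T cells moved with CD4IEL (4 of 4 higher, adjusted p = 9.37e-05, adjusted p = 0.00755 with an estimated correlation). Among them Trgc4 passed in edgeR and Trgc2 (500.1 ± 214.9 against 28.4 ± 32.5 CPM) did not, though the test on shares called Trgc2 higher. The list was lost without mouse 2 (adjusted p = 0.0777) and mouse 3 (adjusted p = 0.136). The alpha chain constant gene Trac stood at 604 ± 173 CPM (mean over cells) in CD4IEL and 625.9 ± 69.3 in Conventional cells.

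Helper-type lists fell with a preset correlation and were lost with an estimated one. For Th17 genes, adjusted p = 1.55e-07 and adjusted p = 0.0812 with an estimated correlation (13 of 14 lower, 0 passing, 7 adjusted over the list alone), with Il17re at 0 against 203.1 ± 184.9 CPM and Ccr6 at 0 against 84.3 ± 112.3. For regulatory T cell genes the pair was adjusted p = 0.00124 and adjusted p = 0.121 with an estimated correlation (9 of 14 lower), with Ctla4 at 238.2 ± 88 against 1503.3 ± 569.3 and Icos at 246.1 ± 104.3 against 941.5 ± 638.6. Follicular helper genes had adjusted p = 0.00118 (7 of 9 lower) and adjusted p = 0.0515 with an estimated correlation. Th2 genes had adjusted p = 0.00671 (3 of 3 lower, Gata3 among them) and adjusted p = 0.109 with an estimated correlation. The CD4 helper lineage list had adjusted p = 0.0243 (9 of 10 lower) and adjusted p = 0.249 with an estimated correlation, and T cell receptor signalling adjusted p = 0.0113 (14 of 24 lower) and adjusted p = 0.322 with an estimated correlation. Lag3 had 438.6 ± 115.2 against 330 ± 292.2 CPM and Il10 3.51 ± 6.09 against 104.4 ± 101.5, and neither passed. edgeR called 7 genes and, with the mouse as block, 7, of which 6 were shared. DESeq2 called 1655 genes, and limma voom 169 higher and 44 lower.

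**Figure D2:**
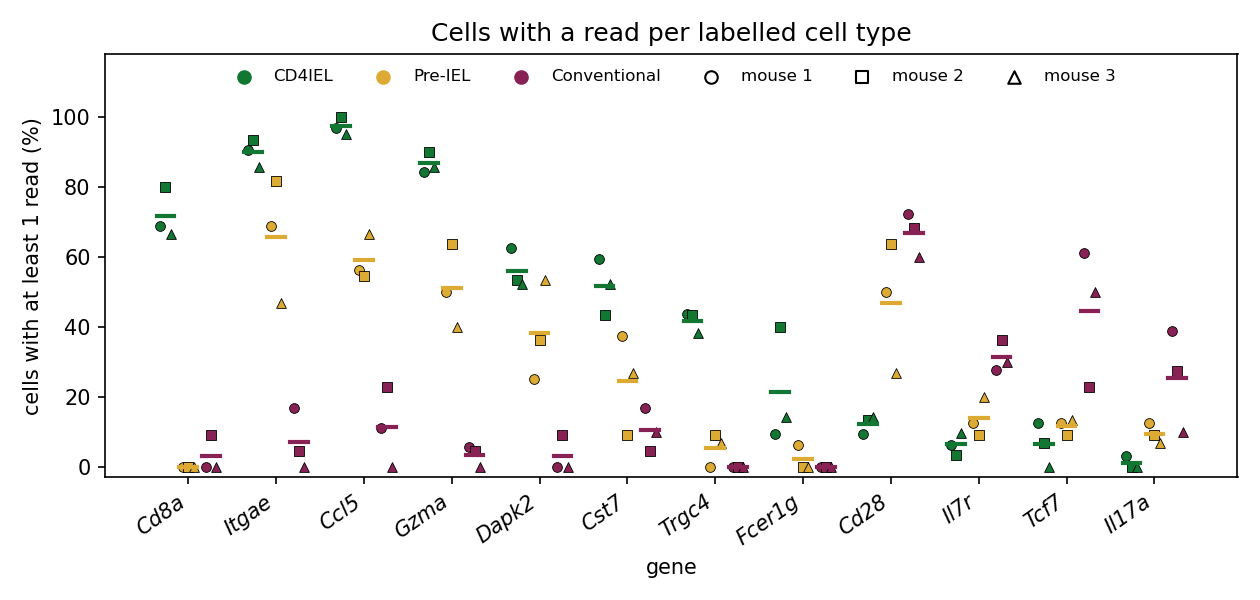
Share of cells in percent with at least 1 read of each gene in CD4IEL, Pre-IEL and Conventional cells; points are the 3 mice and the line is their mean. Ccl5 was read in 81 of 83 CD4IEL and 7 of 50 Conventional cells, Cd28 in 10 and 34.

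Pre-IEL were compared with Conventional cells (42 against 50 cells). Itgae was read in 27 and 4 cells, 774 ± 283.2 against 30.2 ± 52.1 CPM, and Gzma in 21 and 2, 1395.8 ± 892.7 against 551.7 ± 954.9. Both passed the test on shares (adjusted p = 1.39e-05 and 0.00185), which was chosen after seeing the data, and neither passed in edgeR (Itgae adjusted p = 0.254). With the mouse as block that test called 14 genes, Jaml and Ccl5 (adjusted p = 0.0102 each) and Dapk2 (0.0291) among them. Other values that did not pass in edgeR were Dapk2 at 227.5 ± 110.6 against 9.3 ± 16.1, Efhd2 at 263.6 ± 106.3 against 29.3 ± 25.9, Cst7 at 155.6 ± 136.1 against 34.7 ± 42.4 and Jaml at 264.8 ± 284.5 against 6.04 ± 10.5 on the higher side. On the lower side were Cpe (0 against 307.8 ± 196.4, 0 against 6 cells, at least 996.2-fold), Tm9sf2 (54.3 ± 47.6 against 539.2 ± 749), Txlna (0 against 253.7 ± 244.7), Trappc9 (0 against 251.5 ± 342.4) and Ece1 (18 ± 27.9 against 280.8 ± 113.8). Gzmb had 1324.4 ± 978 against 294.2 ± 359.9, Ctla4 1016.2 ± 786.3 against 1503.3 ± 569.3, Lag3 69.3 ± 51.1 against 330 ± 292.2, Il10 167 ± 211.4 against 104.4 ± 101.5 and Foxp3 145.5 ± 239.2 against 0 (2 of 42 cells).

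Recirculating and naive-like genes fell in Pre-IEL (14 of 14 lower, camera adjusted p = 1.15e-12, adjusted p = 0.00257 with an estimated correlation, without mouse 1, adjusted p = 0.184 with an estimated correlation), 0 passing over all genes and 2 adjusted over the list alone. Cytotoxic genes rose (17 of 23 higher and 2 lower, adjusted p = 2.41e-05, adjusted p = 0.226 with an estimated correlation). So did residency genes (15 of 21 higher, adjusted p = 1.37e-05, adjusted p = 0.226 with an estimated correlation), Itgae and Jaml among them. Proliferation genes rose (21 of 24 higher, adjusted p = 2.41e-05, adjusted p = 0.482 with an estimated correlation), with Mki67 at 57.3 ± 61.9 against 0 CPM (4 of 42 cells) and Birc5 at 62.7 ± 59.1 against 0. Th1 genes rose (10 of 13 higher, adjusted p = 0.0141, adjusted p = 0.35 with an estimated correlation). Mitochondrially encoded genes, a sign of RNA quality, moved the other way (12 of 13 lower, adjusted p = 0.00709, adjusted p = 0.557 with an estimated correlation), mt-Nd5 at 840.5 ± 63.5 against 1830.4 ± 431.9 and mt-Co1 at 3694.3 ± 652.9 against 5448.8 ± 825.2 CPM. Heat shock and dissociation genes, a sign of handling stress, had higher values without a call (13 of 14, adjusted p = 0.0831), Hspa8 at 5946.5 ± 595.6 against 3301.2 ± 941.5 CPM, higher in 3 of 3 mice. edgeR called 0 genes, with 1118 at an unadjusted p under 0.05, DESeq2 1614, limma voom 23 and the share of cells 2.

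CD4IEL and Pre-IEL (83 against 42 cells) differed in 1 gene, Cd8a, at 1253.5 ± 268.7 CPM against 0 (60 against 0 cells, at least 4057.1-fold higher, edgeR adjusted p = 1.58e-07). Values that did not pass were, on the higher side, Fcer1g at 472.9 ± 348 against 1.9 ± 3.3, Klrd1 at 336.2 ± 230.1 against 0, Swap70 at 173.5 ± 78.8 against 0 and Trgc4 at 411.5 ± 32.1 against 41.4 ± 63.2. On the lower side were Il27ra at 142.8 ± 27.1 against 467.7 ± 126.6, Il1r2 at 0 against 260.2 ± 253.9, Podnl1 at 2.93 ± 4.4 against 251.5 ± 133.3 and Tinf2. Itgae had 2098.2 ± 250.8 against 774 ± 283.2, Lag3 438.6 ± 115.2 against 69.3 ± 51.1, Ctla4 238.2 ± 88 against 1016.2 ± 786.3 and Icos 246.1 ± 104.3 against 1043.2 ± 355. Markers of γδ and CD8αβ T cells rose (4 of 4 higher, camera adjusted p = 0.00036, adjusted p = 0.0319 with an estimated correlation, and from 0.147 to 0.487 without 1 mouse). Cytotoxic genes rose (21 of 23 higher, adjusted p = 1.81e-07, adjusted p = 0.109 with an estimated correlation), 6 of them adjusted over the list alone against 0 over all genes. Residency genes were called up (adjusted p = 0.0257, adjusted p = 0.418 with an estimated correlation).

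Called lower in CD4IEL than in Pre-IEL were proliferation (21 of 24 lower, camera adjusted p = 8.78e-06, adjusted p = 0.321 with an estimated correlation), Th17 (12 of 14, adjusted p = 0.00103, adjusted p = 0.327 with an estimated correlation), with Il17f at 0 against 381.7 ± 530.7 CPM, and regulatory T cell genes (10 of 14, adjusted p = 0.00261, adjusted p = 0.22 with an estimated correlation). So were Th2 (adjusted p = 0.00384, adjusted p = 0.162 with an estimated correlation), follicular helper (adjusted p = 0.00757, adjusted p = 0.162 with an estimated correlation) and T cell receptor signalling genes (19 of 24, adjusted p = 0.0346, adjusted p = 0.418 with an estimated correlation). Heat shock and dissociation genes, a sign of handling stress, were also lower (11 of 14, adjusted p = 0.00384, adjusted p = 0.349 with an estimated correlation). Mitochondrially encoded genes, a sign of RNA quality, had higher values without a call (12 of 13, adjusted p = 0.171), mt-Co1 at 5550.3 ± 1416.3 against 3694.3 ± 652.9 CPM and mt-Co2 at 3036.1 ± 407.4 against 1843.8 ± 280.3, both higher in 3 of 3 mice. edgeR called 1 gene, with 1057 at an unadjusted p under 0.05, DESeq2 1617, limma voom 110 and the share of cells 1 (6 with the mouse as block).

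Whether the tetramer contrast itself differed between types was tested as a difference of contrasts. None of the 8835 genes passed in edgeR for CD4IEL less Conventional (smallest adjusted p = 0.271, 1092 at an unadjusted p under 0.05, DESeq2 1534, limma voom 1.3% of the genes tested), CD4IEL less Pre-IEL (0.287, 910, DESeq2 1520, limma voom 35) or Pre-IEL less Conventional (0.265, 1100, DESeq2 1571, limma voom 16). Nearest the threshold for CD4IEL less Conventional were Rock2, Asb7, Maip1, Atrn and Fam136a on the higher side and Il27ra, Tinf2, Errfi1 and Chuk, a kinase of the NF-kappaB pathway, on the lower.

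T cell receptor V genes were read because the tetramer selects cells by their receptor. A Trav family was called in 125 cells, and a Trbv gene with it in 106. The chance that 2 cells of a mouse share a Trbv gene was 8.25% ± 3.02 among tetramer-positive and 9.99% ± 1.38 among tetramer-negative cells (n = 3 mice, exact permutation p = 0.6). Trbv13-3 (3 of 15 cells), Trbv5 (5 of 20) and Trbv4 (2 of 5) were the most frequent in tetramer-positive cells of mice 1, 2 and 3, and Trbv19 (8 of 34), Trbv13-1 (9 of 33) and Trbv5 (7 of 30) in tetramer-negative cells. With at least 50 counts for a call the index was 38.9% ± 53.1 against 9.68% ± 4.15 (exact permutation p = 0.7).

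Shares of cells with a transcript, after thinning to equal depth, were compared for 14 genes. Gzma was read in 41.7% ± 7.64 of tetramer-positive and 61.7% ± 9.06 of tetramer-negative cells, Ccl5 in 45.8% ± 7.22 and 72.4% ± 1.77, Cd8a in 16.7% ± 7.64 and 45.4% ± 5.78 and Itgae in 46.7% ± 10.4 and 67.2% ± 7.93, each lower in 3 of 3 mice. Il17a was read in 20.8% ± 12.3 and 7.06% ± 3.56, higher in 3 of 3 mice. The exact permutation p was 0.1 for each of these 5 genes, the smallest possible, in a test that leaves out the pairing by mouse. Ctla4 was read in 55.8% ± 9.46 and 48.6% ± 0.19 (exact p = 0.4, and 45.8% and 45% with at least 5 reads), Gzmb in 38.3% ± 12.6 and 50.3% ± 13.4 (exact p = 0.4), Lag3 in 20.8% ± 12.3 and 26.1% ± 7 (exact p = 0.6), Il10 in 6.67% ± 7.64 and 4.27% ± 5.34 (exact p = 0.7) and Foxp3 in 1.67% ± 2.89 and 1.08% ± 1.86 (exact p = 1). These shares are over all cells of a class, whose cell types differ in number.

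Of the 23 lists, 9 passed in none of the 10 contrasts. Inhibitory and anti-inflammatory genes, which include Il10, Ctla4 and Lag3, had 0.386 as their smallest camera adjusted p (20 members tested, Pre-IEL against Conventional). That of the type I interferon response was 0.455, of the TGF-beta response 0.161, of retinoic acid and gut homing 0.0673, of oxidative phosphorylation 0.205 and of glycolysis 0.101. Among markers of other cell types, the smallest adjusted p was 0.0938 for epithelial cells (5 members, tetramer contrast in CD4IEL), 0.342 for B and plasma cells (1 member) and 0.0753 for myeloid cells (4 members). In CD4IEL against Conventional cells the epithelial markers had adjusted p = 0.146, with Epcam at 25.4 ± 37 against 0 CPM (3 cells) and Cdh1 at 41.5 ± 61.9 against 0 (6 cells).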

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

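No test in this part was chosen after its result was seen, except the draws to equal cell numbers and the list tests without 1 mouse. The 5 results below are gene lists whose tetramer contrast differed between cell types by the test of that difference. None held with an estimated correlation.

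In CD4IEL less Conventional cells, cytotoxic and NK-like genes were lower (camera adjusted p = 2.07e-05, adjusted p = 0.256 with an estimated correlation, median log2 difference -4.43). Within that difference, the contrast in CD4IEL had 22 of 23 members lower, 17 of them in 3 of 3 mice. The one in Conventional cells had 12 higher and 3 lower, with equal means for the rest and only 1 higher in 3 of 3 mice. Recirculating and naive-like genes were called higher in the same difference (adjusted p = 8.58e-05; adjusted p = 0.135 with an estimated correlation), although their median log2 difference of -1.13 had the opposite sign and lay close to the median of all genes, -1.07. In CD4IEL less Pre-IEL, cytotoxic and NK-like genes were lower (adjusted p = 0.0249; adjusted p = 0.676 with an estimated correlation). Regulatory T cell genes were higher there (adjusted p = 0.0249; adjusted p = 0.676 with an estimated correlation), as were mitochondrially encoded genes (adjusted p = 0.0249; adjusted p = 0.778 with an estimated correlation).

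In 5 draws of both tetramer classes to equal cell numbers, cytotoxic genes in CD4IEL less Conventional cells passed in 5 (adjusted p at most 0.000549) and, without 1 mouse, in 3 of 3 (at most 0.0186). Recirculating genes there passed in 2 of 5 draws (up to 0.682) and without each mouse (at most 0.0105). In CD4IEL less Pre-IEL, cytotoxic, regulatory T cell and mitochondrially encoded genes each passed in 1 of 5 draws (up to 0.343, 0.706 and 0.981). Without 1 mouse the first and second of these passed in 1 of 3 (up to 0.605 and 0.708), and mitochondrially encoded genes in 0 of 3 (0.139 to 0.232).

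Chance was not excluded for these lists. In CD4IEL less Conventional cells, 11 of 100 splits of the sums gave as many lists as the 2 of the real split (highest other 3). In CD4IEL less Pre-IEL, 5 of 100 splits gave as many as 3 lists (highest other 4). Real counts of 0 are reached by every split and decide nothing. These were the genes of CD4IEL less Conventional (100 of 100 splits, highest other 2), of CD4IEL less Pre-IEL (100 of 100, highest other 1) and of Pre-IEL less Conventional (100 of 100, highest other 2), and the lists of Pre-IEL less Conventional (100 of 100, highest other 5).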

How the results depend on the processing

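The tests on shares of cells, the draws to equal cell numbers, tetramer-negative cells alone and lists without Cd4, Cd8a and Itgae were chosen after results were seen. Calls of genes are given here in percent of the genes tested under the same setting, where 1 of 8835 genes is 0.0113%. With the mouse as replicate block, edgeR percentages were the same in all 10 contrasts, 0.0792% for CD4IEL against Conventional, 0.0113% for CD4IEL against Pre-IEL and 0 elsewhere, as were the list counts (10, 6 and 10 for the contrasts of types). Shares of CD4IEL and Conventional cells kept their side under every alternative that was run. The CD4IEL share was lower by -23.8 percentage points in tetramer-positive cells and ranged from -35 to -16.4 without 1 mouse. That of Conventional cells was higher by 23.9 and ranged from 20.8 to 28.7. For Pre-IEL the difference of -0.147 ranged from -5.9 to 6.24. The Trbv sharing index differed by -1.73, from -3.12 to -0.259 without 1 mouse, and by 29.2 with at least 50 counts for a call.

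Calls of genes moved most with the tool, and the cause was not tested. DESeq2 called 18.9% of genes in the tetramer contrast over types, 12.2% in CD4IEL, 13.5% in Pre-IEL, 12.3% in Conventional cells, 18.7% in CD4IEL against Conventional, 18.3% in Pre-IEL against Conventional and 18.3% in CD4IEL against Pre-IEL. For the differences CD4IEL less Conventional, CD4IEL less Pre-IEL and Pre-IEL less Conventional it called 17.4%, 17.2% and 17.8%. In the same order, limma voom with quality weights called 0.521%, 6.79%, 0.396%, 0.34%, 2.41%, 0.26%, 1.25%, 1.3%, 0.396% and 0.181%. Sums of at least 4 cells gave 0.01%, 0.02%, 0.01%, 0, 0.12%, 0.01%, 0.04%, 0.01%, 0.03% and 0.01%. Without 1 mouse the ranges were 0 to 0.0212%, 0 to 0.0106%, 0 to 0.0106%, 0 to 0.0226%, 0.0344% to 0.0846%, 0.0115% to 0.034%, 0.0115% to 0.0317%, 0 to 0.0212%, 0 to 0.0212% and 0 to 0.0226%. Without a filter on low counts (16204 genes) there were 0.0185% in the tetramer contrast over types, 0.00617% in Conventional cells, 0.13% in CD4IEL against Conventional, 0.00617% in Pre-IEL against Conventional, 0.0309% in CD4IEL against Pre-IEL, 0.0123% in CD4IEL less Conventional and 0.00617% in Pre-IEL less Conventional.

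The tetramer contrast over types had 0.0633% (5 genes) without plate 1 and 0.0126% (1 gene) without plate 3. CD4IEL against Conventional had 0.253% (20 genes) without plate 1, 0.0505% (4) without plate 2, 0.139% (11) without plate 3, 0.192% (17) with a pseudocount of 5 on mean CPM and 0.147% (13) on the authors' normalized values. By shares of cells it had 0.596% (42), and 0.994% (70) with the replicate block. Pre-IEL against Conventional had 0.0113% (1 gene) by mean CPM, 0.0115% (1) in cells with at least 1000 genes, 0.0284% (2) by shares and 0.199% (14) by shares with the block. CD4IEL against Pre-IEL had 0.0226% (2 genes) with RLE factors and 0.0852% (6) by shares with the block. In the first draw to equal cell numbers there were 0.0264% (2 genes) in Conventional cells, 0.0132% (1) for CD4IEL less Conventional and 0.0264% (2) for Pre-IEL less Conventional.

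Counts of lists were 3, 3, 1, 1, 10, 6, 10, 2, 3 and 0 in the order above. With an estimated correlation they were 0, 0, 0, 1, 4, 1, 1, 0, 0 and 0, and with fry 2, 4, 0, 1, 4, 1, 2, 1, 0 and 0. Without 1 mouse they ranged from 0 to 4, 0 to 2, 0 to 3, 1 to 3, 7 to 9, 3 to 7, 5 to 8, 2 to 4, 0 to 2 and 0 to 1. Camera on shares gave 1 list in CD4IEL, 2 in Pre-IEL, 1 for CD4IEL less Conventional and 0 for CD4IEL less Pre-IEL. Sums of at least 4 cells gave 3 lists in Conventional cells and 5 for CD4IEL less Pre-IEL. The first draw to equal cell numbers gave 0 in the tetramer contrast over types, 1 in CD4IEL and 0 in Pre-IEL. It gave 1 for CD4IEL less Conventional, 0 for CD4IEL less Pre-IEL and 2 for Pre-IEL less Conventional. Other draws differed from it. Over all 5, recirculating genes passed in 3 and proliferation in 4 in the contrast over types, and proliferation in 3 in Pre-IEL. Among values of single named genes under the alternatives, 6936 kept their direction and side of the threshold and 460 were past it only under the alternative. Another 36 were past it only in the first fit, and 324 differed in sign, called in neither. Genes called in neither fit count among the 6936, so that number does not show how stable the calls were. The 36 come only from the genes called in the first fit, 7 for CD4IEL against Conventional and 1 for CD4IEL against Pre-IEL. Of the tetramer differences in the share of cells with a transcript, that of Ctla4 moved from 7.23 to 0.865 percentage points with at least 5 reads, and the exact permutation p of Itgae was 0.2 without thinning and with at least 5 reads. Spread between sums limited the calls, since simulated 16-fold changes in the tetramer contrast were recovered in 98% at a coefficient of variation of 0.4 and in 0% at the observed 2.21. Depth was not varied in the simulation.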

Other observations

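Tests chosen after results were seen were those of the lower lean and of the CD4IEL share. So were those of cell numbers, wells and constant gene classes among V gene pairs, and the test of all genes on shares of cells with a read. The splits, the Trav shuffle, the J gene search and the leading constant gene were chosen before their own results were seen. The count of V gene pairs was not in the plan fixed before the data were examined, which compared Trbv genes alone.

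Shares of cells with a read were compared between cell types for single genes. Ctla4, the inhibitory receptor, was read after thinning in 34.3% ± 7.53 of CD4IEL, 67% ± 11.9 of Pre-IEL and 63.8% ± 4.51 of Conventional cells (SD, n = 3 mice). Lag3, another inhibitory receptor, was read in 33.8% ± 6.7, 7.47% ± 6.81 and 26.2% ± 16.9. Il17a was read in 1.19% ± 2.06, 10.2% ± 2.69 and 28.8% ± 15.7. Ifng was read in 24.6% ± 10.3 of Pre-IEL, 11.3% ± 6.32 of CD4IEL and 5.42% ± 5.05 of Conventional cells. The exact permutation p of CD4IEL against Conventional cells was 0.1, the smallest possible, for Ctla4 and Il17a, and 0.6 for Lag3. For Ifng the exact p was 0.1 for Pre-IEL against Conventional cells and 0.2 against CD4IEL, where the share was higher in Pre-IEL in 2 of 3 mice.

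Of 8 genes of the receptor complex and its coreceptor, 3 had the same sign in all 3 mice between CD4IEL and Conventional cells, as values without a test of the group. Cd3g stood at 1397.9 ± 203.9 CPM (mean over cells, n = 3 mice) in CD4IEL and 637.5 ± 171.7 in Conventional cells, and Cd3e at 1034.1 ± 386.7 and 370.7 ± 242.1, both higher in 3 of 3 mice. Cd247, the zeta chain that carries most signalling motifs of the complex, stood at 196.8 ± 44.4 and 501.5 ± 112.7, lower in 3 of 3 mice. The log2 ratio was near 0 for Trac (-0.08), Trbc1 (-0.17), Trbc2 (-0.05) and Cd4 (-0.1), and Cd3d (0.45) was lower in 1 mouse. Fcer1g, whose product can take the place of the zeta chain in some T cells, was read in 18 of 83 CD4IEL and 0 of 50 Conventional cells, with 12 of the 18 from mouse 2 (40% of its CD4IEL, against 9.38% and 14.3% in mice 1 and 3).

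Other splits of the sums were compared with the real one. Chance here means only that type labels fell at random on the sums. The rule that assigned types is not given, and had it used these transcripts, the real split would lead in advance. Excluding chance in this sense therefore cannot show that the types differ beyond the genes that set the labels. For CD4IEL against Conventional cells chance in this sense was excluded for the 7 genes, Cd8a and Itgae among them (1 of 100 splits, highest other 3). The same held for the 10 lists (1 of 100, highest other 9) and the 42 genes by shares (1 of 100, highest other 35). Among the 32 splits that exchanged labels within mice and so kept the animals balanced, 1 gave as many genes (highest other 0), 1 as many lists (highest other 9) and 1 as many as 42 genes by shares (highest other 21). For CD4IEL against Pre-IEL, chance was excluded for the 10 lists (1 of 100, highest other 8, and within mice 1 of 32, highest other 8). For the 1 gene by edgeR it was not excluded over all splits (6 of 100, highest other 1) but was within mice (1 of 32, highest other 0). A count of 1 gene by shares was reached in 9 of 100 splits (highest other 2) and within mice in 4 of 32 (highest other 3), so chance was not excluded for a count of 1. These counts take any gene and do not test Cd8a itself, which was read in 66.7% to 80% of CD4IEL and 0% of Pre-IEL cells of each mouse. For Pre-IEL against Conventional cells, the share of all splits was under 0.05 for the 6 lists (4 of 100, highest other 7). It was also under 0.05 for the 2 genes by shares (2 of 100, highest other 6). Within mice it was not, for those lists (3 of 32, highest other 7) or for those 2 genes (2 of 32, highest other 2). Chance was therefore not excluded for either. A real count of 0, such as the genes of edgeR here (100 of 100, highest other 2), is reached by every split and decides nothing. The real split parts every pair of sums of the same mouse and tetramer class, as 12 of the 100 splits did, and the others part fewer. Among those 12, only the real one reached its count for both contrasts of CD4IEL (highest others 0 genes each, and 9 and 8 lists), while 2 of the 12 reached the 6 lists of Pre-IEL against Conventional cells.

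For the tetramer contrast over types, chance was not excluded for the 3 lists (5 of 100, highest other 3), and the count of 0 genes decides nothing (100 of 100 splits, highest other 1). Among the 8 drawn splits that parted as many pairs of the same mouse and type, 1 gave as many lists (highest other 2). Within a type the splits were too few for a share under 0.05. CD4IEL had 3 lists as the real value (1 of 10 splits, highest other 0) and 0 genes (10 of 10, highest other 1), Conventional cells 1 list (3 of 10, highest other 3) and 0 genes (10 of 10, highest other 1), and Pre-IEL 1 list (5 of 10, highest other 3) and 0 genes (10 of 10, highest other 1).

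Single genes leaned lower in tetramer-positive sums, with a median log2 change of -0.87 in CD4IEL, where DESeq2 called 47 genes higher and 1030 lower. The tables argue against TMM normalization as the whole cause, since RLE factors left a median of -0.493. In 5 draws of both classes to equal cell numbers, at most 46.7% of DESeq2 calls were lower and the median change was 0. The lean may therefore come from the fewer cells in tetramer-positive sums, in which a gene read in few cells is more often at 0. No biological explanation was tested for it.

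The lower CD4IEL share among tetramer-positive cells was weighed against some technical sources. Not covered were the tetramer sort and later cell filters, which can themselves set the shares. The 4 plates held 19, 10, 16 and 8 tetramer-positive cells, against 30, 33, 29 and 30 tetramer-negative ones. The tables argue against cells with few detected genes, since without cells under 1000 genes the difference was -25.2 percentage points, and against a difference between plates, since the share was lower in 4 of 4 plates. Weaker tetramer staining through fewer receptors stays open: of Trac, Trbc1, Trbc2 and Cd4, 0 genes were lower in CD4IEL than in Conventional cells in all 3 mice, but surface protein was not measured and tetramer class was tied to well rows. A candidate explanation is that cells with this specificity may be held more often in the Conventional state, which was not tested here.

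V gene pairs were counted within mice. Among tetramer-negative cells the share with a pair seen again in the same mouse was 34.5% ± 20.8 and among tetramer-positive cells 6.06% ± 10.5 (n = 3 mice; exact permutation p = 0.2). Tetramer-negative CD4IEL shared a pair in 18 of 42 cells, Pre-IEL in 7 of 17 and Conventional cells in 2 of 14. The most frequent pair, Trav5 with Trbv13-1 in mouse 2, was called in 4 CD4IEL and 4 Pre-IEL cells over 4 plates, and Trav4 with Trbv19 in mouse 1 in 5 CD4IEL cells over 3 plates.

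Cells of 1 mouse that share both a Trav family and a Trbv gene were common among tetramer-negative cells, 27 of 73 (37%, Clopper-Pearson 26% to 49.1%). They were rare among tetramer-positive cells, 2 of 33 (6.06%, 0.74% to 20.2%). These intervals pool mice and treat cells as independent, although a cell counts only if another of its mouse has its pair. They therefore cannot weigh the classes against each other. For the cells sharing a pair, the tables argue against the larger number of tetramer-negative cells. Type-matched draws of tetramer-negative cells had a median of 6 sharing cells, and 2 or fewer in a share of 0 of the draws (one-sided p = 0.0001 by these draws, the smallest possible). The tetramer-positive count of 2 was held fixed, so its own sampling error is not covered. For 4 tetramer-positive cells there was no tetramer-negative partner of their mouse and type. The draws take cells rather than mice, so they do not cover the spread between mice. By mouse the exact permutation p was 0.2, and 13, 12 and 2 tetramer-negative cells of mice 1, 2 and 3 shared a pair. The tables also argue against chance pairing of common V genes (one-sided p = 0.0013 by Trav shuffles), in a count of pairs that was not planned. For the 2 most frequent pairs alone, they argue against carry-over between neighbouring wells (as many neighbours in 0.4199 and 0.6855 of random draws), the others being untested. Expanded clones stay open, since J gene calls were made in 0 cells and the leading constant gene gave 0.289 of shuffles. The class of constant genes was equal in 43 of 45 cell pairs (one-sided p = 0.0001 by shuffles, the smallest possible). But these classes were chosen after all 8 cells of the most frequent pair were seen to carry both genes, so that value cannot decide.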
